A study of Mus musculus with 4 samples.

How the data were processed

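RNA from area CA1 of the hippocampus of handled control mice was measured on 4 arrays of 1 colour, 1 sample at each of 1, 2, 4 and 6 hours after the last shock of the experimental mice, per the labels. The samples formed 1 group of 4, the handled controls. In the deposited table each row is a probe set and each value an intensity on a linear scale. From the deposited values themselves, each array had been scaled to a common level, since the mean after trimming 2% at each end was 500.3 in each column. The array software, the labelling protocol and the scan settings are not given in the sources used here, and detection calls were not used here. The term 2nd in the sample titles is not explained there, and no batch, slide or date was used.

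The table held 12488 probe sets, of which 66 controls were kept out of all tests. Genes were named from the array's annotation table. Of 12422 probe sets, 10833 had 1 gene symbol, 396 had several and 1193 had none, and the last 2 kinds were not named. Of the probe sets with 1 symbol, 10817 were matched by gene identifier to the reference gene table of the assembly GRCm38.p6, from which current symbols but no coordinates were taken. The array was designed on older gene models, the part of the transcript that a probe set targets was not used here, and different probe sets of a gene can disagree. Levels of different probe sets were not compared with each other.

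The 4 columns were quantile normalized, values under the 20th percentile (a signal of 35.1) were set to that floor, and log2 was taken. A probe set was tested if its mean log2 value was at or above the 40th percentile, which left 7453, 6742 of them with 1 symbol. A probe set at the floor in a sample has only an upper bound there. The trend was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with time as a linear term coded so that the coefficient is the fitted log2 change from 1 to 6 hours. With 4 samples this leaves 2 residual degrees of freedom. P-values were two-sided and adjusted by Benjamini and Hochberg, and they measure the spread between these samples, which the labels do not tie to separate animals. Pairs of samples were compared without a test, by the number of tested probe sets 2-fold or more apart. A limma fit of each sample against the other 3, with the same form of prior estimated anew in each fit, was added after the data had been seen. The single sample has no spread of its own in it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

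A total of 24 gene lists were fixed before the data were examined. They covered clock genes, immediate-early genes, glucocorticoid-responsive genes, NF-kappaB, heat shock and chaperones, synaptic plasticity, histones and histone acetylation, oxidative phosphorylation, cytosolic ribosomal proteins, male and female markers, and 14 sets of markers for CA1, CA3 and CA2, dentate gyrus, interneurons, astrocytes, oligodendrocytes, microglia, endothelium, choroid plexus, meninges, blood, thalamus, neocortex and neurons in general. Some genes stand on more than 1 list. Each gene entered by its probe set with the highest mean. The 21 lists with at least 5 tested members were tested for a trend with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. At an estimated correlation camera takes its degrees of freedom from the residuals of the samples, at a preset one from the number of genes. Fry tests whether the genes of a list move on balance 1 way and does not compare the list with other genes. The median difference of each list in each sample was also ranked among 10000 random lists of the same size matched on mean expression.

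Genes were named by a rule set before the data were examined. It took the 12 with a positive and the 12 with a negative trend that passed, or, where fewer passed, those with the smallest p. For each sample it took the 3 probe sets furthest above and the 3 furthest below the mean of the other 3, among those above the floor in all samples. For each list described it took the 4 members with the largest range, here among tested members, and it added 20 preset genes, of which Arc, Nfkb1 and Hbb-b1 had no probe set under that symbol in the annotation used here. Among genes named by trend, by sample or as preset, some rest on probe sets counted here as marked for cross-hybridization. They are Sema4b, Pklr, Hltf, Tradd, Junb, Gfap and the dimmer Csnk1d probe set. Of those named by trend they are Entpd6, Erdr1, Prp2, Phf7, Itpr2, Zcchc7 and Hat1. Other genes are named where a value was singled out afterwards: Mobp in the report, and genes of the closing section.

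The fits were tested on simulated data with the real means and the residual spread of the trend fit, and with noise drawn independently for each probe set. For the trend, 200 of 7453 probe sets were changed, and 3 others were called. For 1 sample against the other 3, the fit called 0% of probe sets changed by 1 log2 unit, 51.25% of those changed by 2 and 82.5% of those changed by 4, with 5 other calls. The residuals of the trend fit include the 1-hour sample, while the real fit of that sample took its spread from the other 3. The rates for 1 sample therefore do not carry over to it. Camera called 5 of 5 lists of 20 genes shifted by 0.5, with 0 other calls. Because the simulated genes varied independently, this does not show how camera at a preset correlation behaves where genes vary together. In the real fit the estimated correlation reached 0.26, for the choroid list.

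The alternatives were the values as deposited, scaling to equal medians, a floor at the 40th percentile, a pseudocount in place of the floor, no filter, a filter at the 60th percentile, leaving out probe sets marked for cross-hybridization, time as log2 hours, as ranks or as an earlier and a later pair, 3 other forms of the test, the mean of a gene's probe sets, a 1.5-fold threshold, and leaving out each sample in turn. Added after the data had been seen were the fit of each sample against the others, the pairs and lists without the 1-hour sample, the choroid list without Ttr, and an estimated correlation between genes joined to the list test without each sample in turn and to that of an earlier and a later pair. So was a correction of each pair of arrays after quantile normalization, by the factor that left fewest 2-fold differences or by a lowess curve on intensity.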

Results

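The series holds 4 expression arrays of total RNA from area CA1 of the hippocampus, the region whose pyramidal neurons give the main hippocampal output. The mice were young C57BL/6J males, an inbred laboratory strain, and all 4 samples were controls that had been handled and given no other treatment. They served an experiment in which other mice received shocks, and the control RNA was taken 1, 2, 4 and 6 hours after those mice had had their last shock. There was 1 sample at each time, and no shocked sample was analysed here. The labels do not say whether a sample was 1 mouse or a pool, so the spread between samples mixes time, animals, dissection and array. The precision is limited by the number of arrays. Values are the deposited signal on a linear scale unless they are given as log2 differences, and a difference is stated for a sample against the mean of the other 3, with the SD of those 3.

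The state of the RNA was read from control probe sets that target the 5' end, the middle and the 3' end of 2 housekeeping transcripts, Gapdh, a glycolytic enzyme, and beta-actin, a cytoskeletal protein. For Gapdh the 3' signal over the 5' signal was 4.52 in the 1-hour sample, against 1.18, 1.37 and 1.20 in the 2-, 4- and 6-hour samples. The 5' Gapdh signal itself was 8571 in the 1-hour sample and 26015, 24344 and 27757 in the others. For beta-actin the same ratio was 2.34 in the 1-hour sample and 2.00, 1.80 and 1.76 in the others. Its 5' signal was 16054 in the 1-hour sample and 16715, 18391 and 18254 in the others. The signal of a B1 repeat, a short interspersed element carried by many mouse transcripts, was 100096 in the 1-hour sample and 66309, 69379 and 63399 in the others. Bacterial and phage control transcripts, measured by 9 probe sets, were all higher in the 1-hour sample, by 0.49 ± 0.14 on the log2 scale (mean and SD over the 9 probe sets), a factor of 1.41. No test was made, since each time had 1 array.

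**Figure D1:**
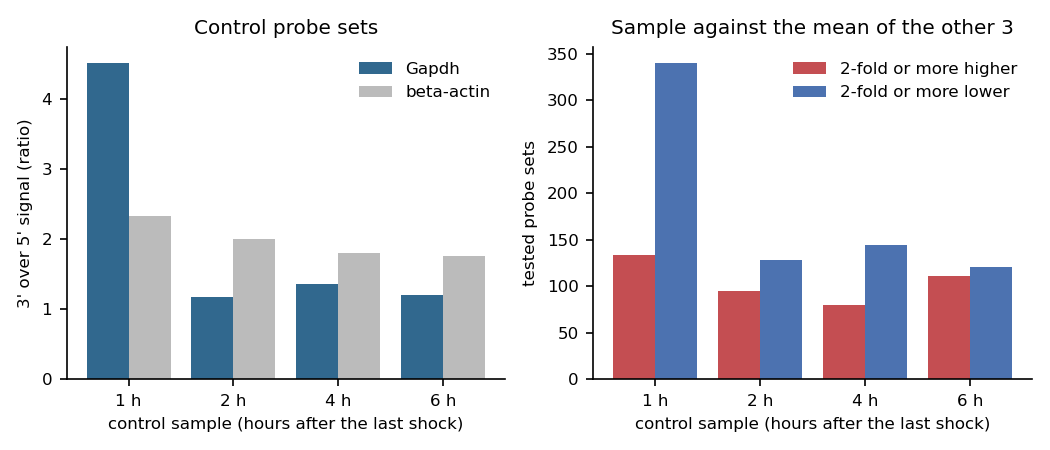
Left, the signal of the 3' control probe set over that of the 5' control probe set of Gapdh and beta-actin (ratio, linear axis) in each of the 4 control samples. Right, the number of tested probe sets that lay 2-fold or more above or below the mean of the other 3 samples; the 1-hour sample had a Gapdh ratio of 4.52 and 340 lower probe sets.

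The first comparison asked how far the control samples lay from each other. Transthyretin (Ttr), a carrier of thyroid hormone and retinol that the choroid plexus makes in large amounts, was far higher in the 1-hour sample than in the others. Its signal was 2246 in the 1-hour sample and 199, 353 and 143 in the 2-, 4- and 6-hour samples, 10.5-fold above their mean (log2 difference 3.39, SD of the other 3 0.67). Sema4b, a membrane semaphorin, was 697 in the 1-hour sample and 147 to 192 in the others (2.04, SD 0.17). Pklr, the pyruvate kinase of liver and red blood cells, was 376 at 1 hour and 242 at 6 hours against 55.2 and 65.5 at 2 and 4 hours. At the low end of the 1-hour sample stood Rcc2, a regulator of chromosome condensation, with 43.1 against 269 to 320 (-2.80, SD 0.14), and Gnao1, the alpha subunit of the abundant neuronal G protein Go, with 43.9 against 280 to 323 (-2.79, SD 0.12). Gga1, an adaptor of Golgi sorting, had 47.2 in the 1-hour sample but also 102 in the 4-hour sample, against 488 and 618 in the 2- and 6-hour samples. All of these 1-hour differences stand beside the Gapdh 3' over 5' ratio of 4.52 in that sample.

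In the other samples the genes named by the same rule were of many kinds. In the 2-hour sample Tanc1, a postsynaptic scaffold, Sin3b, a transcriptional corepressor, and Abhd17a, an enzyme that removes palmitate from synaptic proteins, lay 1.88, 1.86 and 1.79 above the other 3 on the log2 scale (SD of those 3, 1.19, 0.99 and 0.84). Ccrl2, an atypical chemokine receptor, Fcgbp and Pdzk1ip1 lay at -2.45, -2.40 and -2.32 there (SD 0.40, 0.49 and 0.37), with signals of 42, 40.5 and 61.2. In the 4-hour sample Rps6kb2, a ribosomal S6 kinase, had a signal of 337 against 72.7 to 90.6 (2.08, SD 0.16). Csnk1d, the casein kinase 1 delta that phosphorylates period proteins, and Tradd, an adaptor of the tumour necrosis factor receptor, lay at 2.06 and 2.05 in that sample (SD 0.99 and 1.12). This Csnk1d probe set had 65.6, 253, 573 and 167 in the order of hours, while the brighter one that entered the clock list had 1933, 2796, 2341 and 2299. Bcl2l11, a trigger of apoptosis, Hltf and Tuft1 lay at -2.36, -2.29 and -2.24 (SD 0.27, 0.62 and 0.24), with signals of 39, 40.2 and 51.9. In the 6-hour sample Capn1, a calcium-dependent protease, Tollip, a regulator of Toll-like receptor signalling, and Gga1 lay at 2.41, 2.21 and 2.21 (SD 0.58, 1.19 and 1.71). Hrh2, the histamine H2 receptor, Cog5, a part of the Golgi tethering complex, and Il15ra, the interleukin 15 receptor alpha chain, lay at -2.55, -2.36 and -2.30 (SD 0.49, 0.54 and 0.46).

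Of 7453 tested probe sets, the number that differed by 2-fold or more was 604 between the 1- and 2-hour samples, 612 between 1 and 4 hours and 652 between 1 and 6 hours. It was 367 between 2 and 4 hours, 299 between 2 and 6 hours and 355 between 4 and 6 hours. The mean was 623 over the 3 pairs with the 1-hour sample and 340 over the 3 without it, a ratio of 1.83, and the median over all 6 pairs was 485.5. Across probe sets, which are not independent replicates, Pearson's r of the log2 values was 0.927 to 0.933 in the pairs with the 1-hour sample and 0.955 to 0.961 in the others. In the 1-hour sample 133 probe sets lay 2-fold or more above the mean of the other 3 and 340 lay as far below. The corresponding numbers were 95 and 128 in the 2-hour sample, 80 and 144 in the 4-hour sample, and 111 and 120 in the 6-hour sample.

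A limma fit of each sample against the other 3, added after the values had been seen, took the spread from those 3 and assumed that the single sample varied as they did. The 1-hour sample has no replicate, so the fit describes how far single arrays lay from the others and does not test the 1-hour time. In the 1-hour sample 175 probe sets had an adjusted p under 0.05, 18 higher and 157 lower, and 1176 had an unadjusted p under 0.05. In the 2-, 4- and 6-hour samples 0 did, with 197, 206 and 169 at an unadjusted p under 0.05. In those fits the 3 samples that gave the spread included the 1-hour sample, which lay furthest out. The counts of the 4 samples are therefore not on an equal footing. The number at 1 hour moved with the handling of low values. With the floor set at the 40th percentile it was 3, and with no filter on low values it was 365, of which 11.0% were lower. On the values as deposited it was 272, of which 79.8% were lower, and with equal medians 222, of which 78.4% were lower, against 89.7% of the 175.

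The spread of each gene over the control samples was wide for a minority of probe sets. The median SD over the 4 samples was 0.25 on the log2 scale, and 1331 probe sets (17.9%) had a range of 1 log2 unit or more. The 1-hour sample was the highest or the lowest value in 933 of these (70.1%) and the lowest in 530. Over the 2-, 4- and 6-hour samples alone, the median SD was 0.20 and 674 probe sets (9.04%) had such a range. Genes often used to follow neuronal activity differed in their spread. Junb, a transcription factor induced by activity, had a range of 1.36 on the log2 scale. Egr1, a transcription factor induced by synaptic activity, had signals of 1572, 1886, 1986 and 1787 in the order of hours (SD 0.14 on the log2 scale, as for every SD here), Nr4a1, an activity-induced nuclear receptor, had 662, 579, 771 and 720 (SD 0.19), and Fos had 340, 257, 300 and 189 (SD 0.38). Mbp, the myelin basic protein, had 7347, 7892, 9392 and 9529 (SD 0.20), and Gfap, the filament protein of astrocytes, 2283, 1692, 1715 and 1632 (SD 0.22). Rel, a subunit of NF-kappaB, lay below the floor of 35.1 in all 4 samples, and Prox1, a marker of dentate granule neurons, had 46.5, 56.1, 25.1 and 59.8, below the filter for tests. Eif2s3y, a Y-linked gene, was the 1 tested member of the male and female marker list and had 163, 90.4, 158 and 156.

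Among the preset clock genes, several had their highest or lowest value in the 1-hour sample, beside its Gapdh ratio of 4.52. Per1, a repressor of the circadian clock, had 152 in the 1-hour sample and 452, 482 and 465 at 2, 4 and 6 hours (log2 difference -1.60, SD of the other 3 0.06). Rora, an activator of the clock, had 60.9 against 195 to 225, and Cry2, a repressor, 269 against 512 to 617. Nr1d1, the nuclear receptor that represses Arntl, had 656 against 282 to 328 (1.13, SD 0.12), and Cry1 had 830 against 366 to 477. Dbp, a clock output transcription factor, had 785, 308, 465 and 693 at 1, 2, 4 and 6 hours. Arntl, the activating partner of Clock, had 418, 610, 549 and 435, and Per2 had 141, 114, 120 and 146. Of 16 tested members of the clock list, 9 were higher and 7 lower in the 1-hour sample, with a median of 0.17 and a mean of -0.14. Over the 2-, 4- and 6-hour samples 1 of 16, Dbp, had a range of 2-fold or more.

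**Figure D2:**
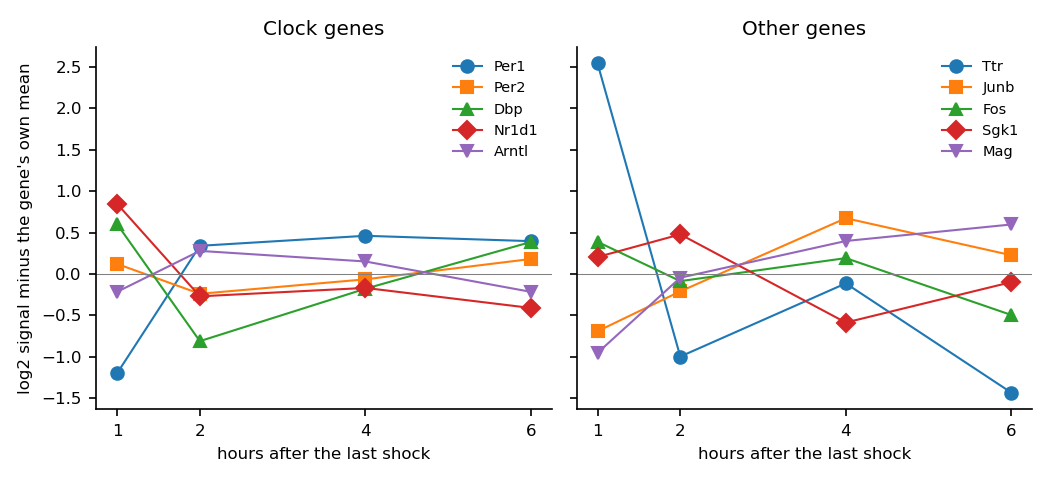
Log2 signal of 10 named genes in each control sample, minus the gene's own mean over the 4 samples, against hours after the last shock; each point is 1 sample, with no replicate. Per1 was lowest and Nr1d1 and Ttr were highest at 1 hour.

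Stress and activity genes were then compared as preset lists. In the 2-hour sample the glucocorticoid-responsive list, which follows corticosteroid hormones, lay at a median log2 difference of 0.24, with 11 of 15 members higher (99.8th percentile of 10000 random lists of the same size and mean expression). In the 6-hour sample it lay at -0.16, with 12 of 15 lower (1.94th percentile). Sgk1, a kinase induced by corticosteroids, had 1132, 1390, 667 and 940 in the order of hours, Tsc22d3, which encodes a glucocorticoid-induced leucine zipper, had 187, 156, 205 and 88.2, and Cdkn1a, an inhibitor of the cell cycle, had 144, 166, 211 and 96.0. Fkbp5, a chaperone of the glucocorticoid receptor, had 836, 1162, 855 and 1281. The heat shock and chaperone list lay at 0.25 in the 2-hour sample (10 of 15 higher, 99.96th percentile) and at -0.23 in the 4-hour sample (5 of 15 higher, 0.07th percentile). Without the 6-hour sample its 2-hour value was 0.16. Pdia6, a protein disulfide isomerase, had 282, 572, 239 and 503, Dnajb1, a cochaperone, 700, 1018, 844 and 596, Hspa1a, the inducible Hsp70, 662, 583, 442 and 385, and Hspe1, a mitochondrial chaperonin, 2480, 1750, 2346 and 1395. The NF-kappaB list lay at 0.23 in the 2-hour sample (7 of 9 higher, 96.9th percentile). Without the 1-hour sample this was 0.47 (99.98th percentile), without the 6-hour sample 0.12, and with the mean of all probe sets of a gene it was 0.095. In the 6-hour sample the list lay at -0.25 (2.82nd percentile), and at -0.31 (0.72nd) without the 1-hour sample. Its members included Traf2, with 331, 684, 547 and 393, Ikbkb, with 137, 221, 122 and 131, Ikbkg, with 377, 333, 301 and 183, and Nfkbia, the inhibitor of NF-kappaB, with 772, 981, 667 and 693. The immediate-early list lay at -0.01, 0.07, 0.12 and -0.09 in the 1-, 2-, 4- and 6-hour samples, within the middle 95% of random lists each time, but the 6-hour value was -0.13 (2.33rd percentile, outside) without the 1-hour sample. Among its members Nr4a2 had 314, 955, 934 and 549, Egr2 180, 257, 193 and 93.2, Junb 339, 493, 885 and 660, and Ier3 109, 154, 173 and 261. These percentiles describe 4 single samples and are no test, and they take genes of a list as independent.

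Neuronal and mitochondrial lists differed in the 1-hour sample, again beside its Gapdh ratio of 4.52. The synaptic plasticity list lay at -0.38 (10 of 15 lower, 0.10th percentile) and the generic neuron list at -0.42 (8 of 12 lower, 0.16th percentile). Grin2b, an NMDA receptor subunit, had 24.4 at 1 hour, below the floor, and 410, 357 and 306 in the others. Grin2a, another such subunit, had 67.1, 205, 49.1 and 206 in the order of hours, and Gria3, an AMPA receptor subunit, 161, 508, 312 and 414. Syp, a synaptic vesicle protein, had 618, 1186, 717 and 1271. Map2, a dendritic microtubule protein, had 25.4 (below the floor), 338, 103 and 268, Syt1, the calcium sensor of vesicle release, 1092, 2216, 1592 and 2452, Nefm, a neurofilament, 221, 148, 184 and 125, and Eno2, the neuronal enolase, 4524, 6608, 6172 and 7266. With the mean of all probe sets of a gene, the generic neuron median was -0.27. The oxidative phosphorylation list lay at 0.22 in the 1-hour sample (25 of 29 higher, 99.9th percentile), and at 0.33 with arrays scaled to equal medians. Atp5k had 651, 309, 343 and 400, Sdha 753, 631, 471 and 697 and Ndufa2 1714, 1566, 2317 and 1332, while Uqcrc1, a subunit of complex III, went the other way with 2078, 3631, 4247 and 3791. The cytosolic ribosomal protein list lay at 0.17 in that sample (12 of 17 higher, 97.1st percentile), with Rps24 at 35731 against 22328 to 23927, Rps3 at 9977 against 6642 to 8696, Rpl22 at 293, 715, 240 and 559 and Rps29 at 248, 229, 247 and 317. Without the 1-hour sample, each of the others set against the mean of the remaining 2, the synaptic list lay at 0.23 in the 2-hour sample (99.98th percentile), and at 0.04 in the 6-hour sample (81.4th, against 0.17 and 99.2nd with all samples). The generic neuron list then lay at 0.07, -0.04 and 0.01 (86.1st, 24.6th and 63.4th percentile). The oxidative phosphorylation list moved from -0.11, -0.11 and -0.01 in the 2-, 4- and 6-hour samples (0.36th, 1.18th and 44.6th) to -0.05, -0.04 and 0.07 (10.4th, 17.6th and 98.0th).

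Marker lists of cell types that the dissection could hold also differed between samples. The endothelial and pericyte list lay at 0.57 in the 2-hour sample (8 of 10 higher, 99.98th percentile), -0.30 in the 4-hour sample (1.78th) and -0.41 in the 6-hour sample (0.20th). Without the 1-hour sample these were 0.49 (99.96th), -0.15 (13.4th) and -0.33 (0.66th). The 2-hour value was 0.36 with the floor at the 40th percentile and 0.33 without the 6-hour sample. Vwf, a clotting protein of endothelium, had 163, 281, 275 and 99.6 in the order of hours, Eng 1376, 790, 764 and 619, Cdh5, the endothelial cadherin, 129, 122, 132 and 65.1, and Pecam1 178, 160, 30.9 (below the floor) and 155. The oligodendrocyte and myelin list lay at 0.23 in the 6-hour sample (10 of 12 higher, 99.6th percentile), and at -0.19 in the 2-hour sample (0.69th) without the 1-hour sample, against -0.08 with it. The choroid plexus and ependyma list, which includes Ttr, lay at 0.42 in the 1-hour sample (6 of 7 higher, 97.2nd percentile, within the middle 95%). In the 2-hour sample it lay at -0.42 (0.60th), and at -0.23 (6.38th) without the 1-hour sample. The 4-hour sample lay at 0.41 (99.3rd) without the 1-hour sample, against 0.23 with it. Calml4 had 228, 62.8, 86.5 and 142, Igfbp2 465, 531, 597 and 358 and Kl 263, 175, 172 and 252. The thalamus list lay at 0.39 in the 6-hour sample (99.6th percentile), and at 0.22 (95.5th percentile, within the middle 95%) without the 1-hour sample. Its members included Lef1 at 484, 148, 546 and 478, Tcf7l2 at 244, 325, 491 and 443 and Zic1 at 264, 222, 216 and 142, while 3 of its members (Rora, Calb2 and Prkcd) stood on other lists too. In all, 19 of 84 medians lay outside the middle 95% of random lists, 3 in the 1-hour, 7 in the 2-hour, 3 in the 4-hour and 6 in the 6-hour sample. Of the 63 medians of the 2-, 4- and 6-hour samples, 16 lay outside with all samples and 21 without the 1-hour sample, 8 of them in both.

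**Figure D3:**
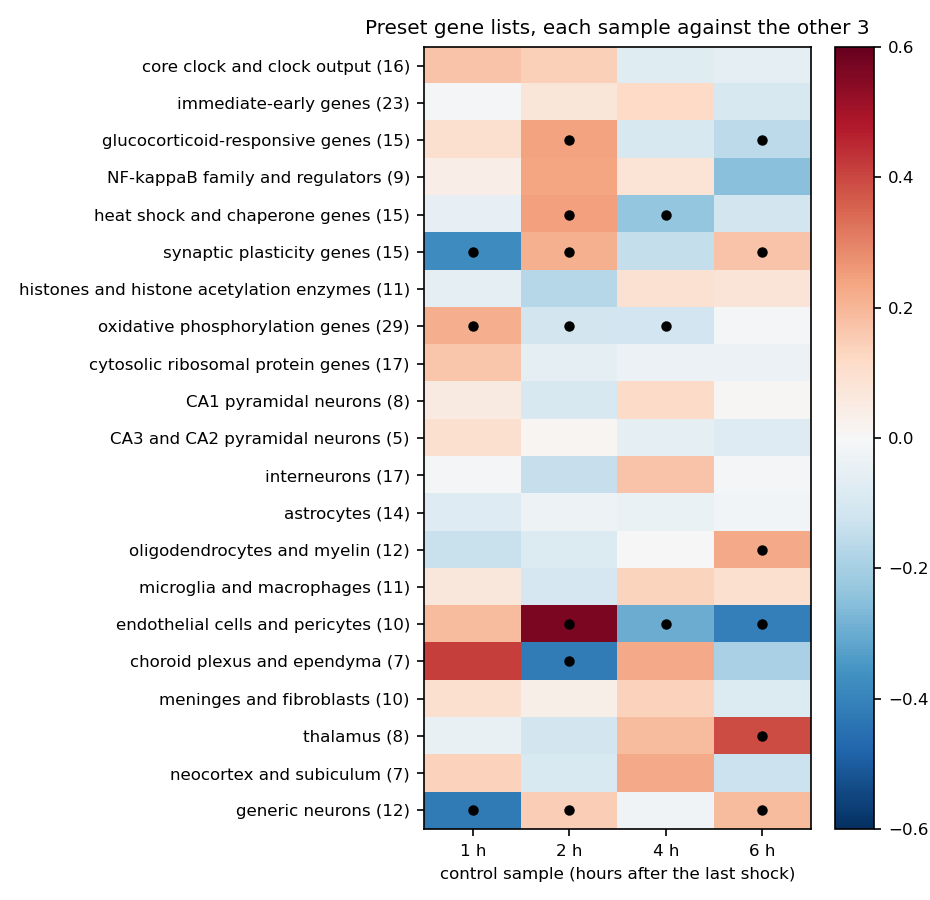
Median log2 difference of each preset gene list in each control sample from the mean of the other 3 (colour), for the 21 lists with at least 5 tested members (number in brackets). A dot marks a median outside the middle 95% of 10000 random lists matched on size and mean expression; 19 of the 84 medians have one.

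The remaining marker lists with a percentile, and the histone list, lay within the middle 95% with all 4 samples. In the 1-, 2-, 4- and 6-hour samples the median was 0.06, -0.10, 0.12 and 0.01 for CA1 pyramidal neurons, 0.10, 0.01, -0.06 and -0.08 for CA3 and CA2 pyramidal neurons, and -0.01, -0.14, 0.17 and -0.01 for interneurons. It was -0.08, -0.03, -0.04 and -0.02 for astrocytes, 0.07, -0.10, 0.13 and 0.09 for microglia and macrophages, and 0.10, 0.03, 0.14 and -0.08 for meninges and fibroblasts. For neocortex and subiculum it was 0.14, -0.09, 0.23 and -0.13. In the list of histones and histone acetylation enzymes it was -0.06, -0.17, 0.09 and 0.08. Without the 1-hour sample several of these left the middle 95%. The 4-hour sample then lay at 0.31 for histones (99.8th percentile), 0.23 for CA1 (98.3rd), 0.19 for interneurons (98.6th) and 0.25 for neocortex and subiculum (97.6th). The 2-hour sample lay at -0.17 for interneurons (1.23rd), -0.21 for microglia (1.21st) and 0.19 for the clock list (98.3rd). The CA1 markers Wfs1, with 2292, 2274, 2797 and 1964, and Man1a, with 1390, 790, 1071 and 913, were measured well above the floor in all samples. With 4 and 3 tested members, the dentate granule and blood lists had medians of -0.21, 0.09, -0.08 and 0.09 and of 0.34, -0.02, 0.11 and -0.41, and no percentile was taken. The alpha-globin gene Hba-a1 had 3185, 2590, 2834 and 2144.

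The main test asked whether any transcript followed a straight line over the 4 times. Mag, the myelin-associated glycoprotein, had 487, 958, 1285 and 1478 at 1, 2, 4 and 6 hours, a fitted log2 change from 1 to 6 hours of 1.40 ± 0.34 (SE), and of 0.79 without the 1-hour sample. Among the 12 with the smallest p and a positive slope were also Lasp1, an actin-binding protein, at 1.90 ± 0.37, Ube2s, a ubiquitin-conjugating enzyme, at 1.37 ± 0.30, and Map1lc3a, an autophagosome protein, at 1.17 ± 0.29 and 0.68 without the 1-hour sample. Capn1, Bcas3, Wdr74, Entpd6, Stx2, Erdr1, Wdr6 and Adprhl2 made up the rest, with fitted changes of 1.23 to 2.81. Of these, Entpd6 fell from 1.57 to 1.00 without the 1-hour sample, and Erdr1 and Adprhl2 fell from 2.45 and 2.48 to 1.60 and 1.45 with the floor at the 40th percentile. Without the 6-hour sample Stx2 rose from 1.42 to 2.15 and Wdr6 from 1.23 to 2.09. With a negative slope stood Cars, the cysteine tRNA synthetase, with 481, 396, 225 and 117 and a fitted change of -2.08 ± 0.33. Zkscan14, a zinc finger gene, had 942, 807, 484 and 363 (-1.45 ± 0.26), Hrh2 307, 311, 169 and 41.5 (-2.87 ± 0.57), and Hat1, a histone acetyltransferase, 525, 585, 300 and 251 (-1.29 ± 0.32). The other 8 were Ccdc186, Prp2, Cog5, Phf7, Aqp8, Itpr2, Eif3e and Zcchc7, with fitted changes of -1.17 to -2.73. With the floor at the 40th percentile Hrh2, Cog5 and Aqp8 went from -2.87, -2.73 and -2.45 to -1.58, -1.32 and -1.21. Without the 6-hour sample they went to -1.54, -1.68 and -1.28, and Phf7 and Zcchc7 from -1.72 and -1.77 to -0.61 and -0.93. None of these passed. With limma, 0 of 7453 probe sets had an adjusted p under 0.05 (lowest 0.74), and 465 (6.24%) had an unadjusted p under 0.05, 266 with a positive and 199 with a negative slope. In simulated data the same fit found 2.5% of probe sets with a log2 change of 1, 28.75% with a change of 2 and 72.5% with a change of 4.

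As groups, oligodendrocyte and myelin genes were the 1 of 21 tested lists that passed for a linear trend, upward. Their mean fitted change was 0.42 and the median 0.24, with 9 of 12 slopes positive (limma's camera, adjusted p = 0.041). With an estimated correlation between genes, camera gave an unadjusted p of 0.083 and an adjusted p of 0.86. Fry gave an unadjusted p of 0.062 and an adjusted p of 0.57. The estimate for this list was -0.08, below the preset 0.01, so the larger p did not come from its genes varying together. That form takes its degrees of freedom from the 4 samples. Besides Mag, Cldn11, a tight junction protein of myelin, had 362, 725, 557 and 875, Gjb1, a connexin, 73.5, 85.7, 102 and 215, and Ugt8a, an enzyme of myelin lipid synthesis, 140, 143, 80.9 and 194. Of the 12 members, 3 had an unadjusted p under 0.05, 1 (Mag) passed when adjusted over the list alone, and 0 passed over all probe sets. Mobp, another myelin gene, had 11695, 8172, 9384 and 10648 on the probe set that entered the list but 322, 1802, 980 and 2031 on another. Without the 1-hour sample the mean change was 0.43 and without the 4-hour sample 0.45, and both passed (adjusted p = 0.010 and 0.024), but with an estimated correlation neither did (0.91 and 0.97). With 3 samples that form has 1 residual degree of freedom and could hardly pass a list, so it decides little here. Without the 6-hour sample it was 0.20 and without the 2-hour sample 0.45, and neither passed (adjusted p = 0.54 and 0.060). Nor did the list pass on the values as deposited (0.065), with equal medians (0.060), with log2 hours (0.080) or with the mean of all probe sets of a gene (0.13).

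The lists next in order had an unadjusted camera p under 0.05 but an adjusted p above it. They were endothelial cells and pericytes (mean fitted change -0.53, adjusted p = 0.081, and -0.34, 0.27 with the floor at the 40th percentile), generic neurons (0.33, 0.13), heat shock and chaperone genes (-0.20, 0.15) and glucocorticoid-responsive genes (-0.23, 0.15). Without the 1-hour sample the generic neuron list turned to a mean fitted change of -0.027 and did not pass. In the same fit the endothelial, heat shock and glucocorticoid lists had a mean fitted change of -0.61, -0.19 and -0.44 and passed (adjusted p = 0.010, 0.037 and 0.010), as the oligodendrocyte list did. Without the 2-, 4- or 6-hour sample none of the 3 passed. Without the 6-hour sample the endothelial list fell to -0.24 and the glucocorticoid list to -0.084 (adjusted p = 0.69 and 0.55), and without the 2-hour sample the latter was -0.14 (0.58). With the 1- and 2-hour samples set against the 4- and 6-hour samples, these 3 lists passed with an adjusted p of 0.048 each. With an estimated correlation, tried on both fits after the data had been seen, 0 lists passed (adjusted p of these 3 lists and the oligodendrocyte list 0.91 and 0.74). The estimates for these lists were -0.11 to -0.05 without the 1-hour sample. In camera that form also takes its degrees of freedom from the samples, 1 without the 1-hour sample, and the preset form does not. With so few a list could hardly pass, so these counts of 0 decide little. With an estimated correlation in the fit of all 4 samples 0 lists passed and 0 had an unadjusted p under 0.05, and fry gave 0 and 1, the astrocyte list (unadjusted p = 0.022). Mean and median of the fitted change differed in sign for the CA1 list (0.03 and -0.09), the astrocyte list (0.10 and -0.01), the histone list (-0.12 and 0.36) and the neocortex list (-0.03 and 0.04). The clock list's mean was 0.06 while camera's direction was downward, and the histone list's mean was negative while camera's direction was upward.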

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

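The tests on the choroid list without Ttr and on the clock genes, the correction of pairs of arrays by a factor or a curve, and the limma fit of each sample against the other 3, were chosen only after the values had been seen. The values in this part were picked out because 1 sample lay far from the other 3, by Dixon's criterion, in which the gap to the nearest sample is set against the whole range. Chance gives about 5% of such groups, and 3 of 25 array measures and list means and 6 of 60 named genes met it. Of the 6 genes, 4 came from the 23 named for their distance in a single sample, which favours them, and 2 from the 37 others.

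The 3' over 5' ratio of Gapdh stood at 4.52 in the 1-hour sample, against 1.18 to 1.37. In the same sample Sema4b lay 2.04 above the mean of the other 3 on the log2 scale, Gfap 0.44 above it, and Rcc2, Gnao1 and Per1 at -2.80, -2.79 and -1.60. Rps6kb2 lay 2.08 above the others in the 4-hour sample. The mean difference over the CA1 pyramidal list was -0.10 in the 2-hour sample, and over the meninges and fibroblast list -0.17 in the 6-hour sample, both far from the other 3 samples but small. The blood list could not be ranked, and its 3 tested members were all lower in the 6-hour sample, where Hba-a1 had 2144.

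The first pattern is the distance of the 1-hour sample from the others, with 340 probe sets 2-fold or more lower and 133 higher. The tables argue against scaling of the arrays as the whole account. With the best factor for each pair, pairs with the 1-hour sample kept 604 to 649 probe sets 2-fold or more apart and the others 297 to 356. With a smooth curve on intensity these were 607 to 667 and 305 to 364. Over all probe sets, with no filter, the lowest pair with the 1-hour sample still exceeded the highest of the others by a factor of 1.23 after the curve. Both corrections were made on values already quantile normalized, which left them little to remove, so they decide little alone. On the values as deposited the mean count of pairs with the 1-hour sample exceeded that of the others by a factor of 1.80. With equal medians this factor was 1.78. The direction of the changes says less. At least 71.1% of these probe sets were lower under all 3 scalings, where a share above 50% had been set as the bound. That bound was too lenient to decide alone, since the share also exceeded it in the 2-, 4- and 6-hour samples (57.4%, 64.3% and 51.9%) and the median of the 1-hour sample lay only 0.03 to 0.07 above the others under the 3 scalings. The filter on low values matters too, because without it 11.0% of the probe sets that the limma fit picked in the 1-hour sample were lower. Loss of 5' transcript parts may account for it, because the Gapdh and beta-actin ratios were highest on that array. For beta-actin, however, the 5' signal was little lower there, with 16054 against 16715 to 18391. Its 3' signal was higher, with 37515 against 32130 to 33401. Other probe sets of the 118 genes concerned lay at 0.124 of the fall of the lowered ones, but the same measure was 0.180, 0.116 and 0.0599 in the 2-, 4- and 6-hour samples, so this ratio did not set the 1-hour sample apart. For 22 of the 130 lowered probe sets there, the other probe sets of the gene were also 2-fold lower (median). In the 2-, 4- and 6-hour samples this held for 2 of 30, 0 of 41 and 4 of 30. Positions of probe sets were not used, so this count does not separate the accounts either. Loss of 5' parts and a true difference at 1 hour therefore cannot be told apart here, the time being carried by 1 sample.

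The second pattern is the choroid plexus list, high in the 1-hour sample. A piece of choroid plexus in that sample is a candidate explanation, and so is its RNA quality. Without Ttr the other 6 tested members, none of which stands on another list, had a median of 0.40, at the 96.1st percentile of matched random lists. By the bounds set, that is neither far enough out to exclude RNA quality nor low enough to exclude choroid tissue. A high rank could not have excluded RNA quality in any case. Other lists lay far out in that sample too, oxidative phosphorylation at the 99.9th percentile and generic neurons at the 0.16th. Calml4 lay at 1.34, Kl at 0.47, Ace at 0.42 and Igf2 at 0.39, with Igfbp2 at 0.00 and Foxj1 at -0.41. Among members too dim for the tests Folr1 had 113 against 41.1 to 55.9 and Aqp1 148 against 66.6 to 126. Of 13 members on the array 7 were tested, and of the rest only Folr1 and Aqp1 are given here. For this list no explanation besides choroid tissue and RNA quality was tested, since time is the only factor the labels name.

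The third pattern is the difference of clock genes between samples. The RNA quality of the 1-hour sample stays open, because over the other 3 samples 1 of 16 clock genes (Dbp) was 2-fold or more apart, against 8.85% of all tested probe sets above the floor (exact binomial p = 0.77, one-sided). Time of day may also contribute. From 2 to 6 hours the 8 genes grouped with Per and Nr1d1 differed by a mean of 0.05, with only 4 of 8 higher at 6 hours. A common peak within each group was assumed. Dbp, at 1.20, differed most among them and weighed heavily in that mean. The 4 grouped with Arntl differed by a mean of -0.33, all 4 of them lower at 6 hours. The difference between these means had an exact permutation p of 0.25 (two-sided, 495 assignments of the genes). If members of a group peak at different hours, this p cannot decide on time of day. Neither explanation could be excluded, and the hour of the day at which RNA was taken is not given in the sources used here.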

How the results depend on the processing

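The counts of pairs without the 1-hour sample, the joint settings with an estimated correlation and all values for the fit of the 1-hour sample against the other 3 were chosen after the data had been seen. No paired analysis was possible because there was a single group. No probe set passed for a trend under the settings that kept all 4 samples, while leaving out 1 sample in turn gave 0 to 3, the 3 being Ttr, Syt11 and Mobp without the 2-hour sample. Those at an unadjusted p under 0.05, 465 in the report, were 721 with no filter, 817 with time as log2 hours, 719 with ranks of time and 231 to 901 with 1 sample left out, lowest without the 1-hour and highest without the 2-hour sample. The 1 list with a trend became 0 on the values as deposited, with equal medians, with log2 hours, with the mean of a gene's probe sets and with an estimated correlation, became 4 with an earlier against a later pair, and was 0 to 4 with 1 sample left out, 4 without the 1-hour sample. With an estimated correlation the 4 became 0 for the pairs, and leaving out any 1 sample gave 0. With 1 sample left out that form has 1 residual degree of freedom. A list could then hardly pass, so this 0 does not count against the lists. The median number of 2-fold differences per pair, 485.5, was 321.5 with a floor at the 40th percentile, 1410.5 with no filter, 137.5 with a filter at the 60th percentile and 1467 with a 1.5-fold threshold, and 355 without the 1-hour sample. Pairs with the 1-hour sample exceeded the others by a factor of 1.83, of 3.79 with the 60th percentile filter, 2.33 with the floor at the 40th percentile and 1.31 with no filter. The number of probe sets with a range of 1 log2 unit, 1331, was 3433 with no filter, 428 with the 60th percentile filter and 667 to 1032 with 1 sample left out. Changes with the filter, the threshold and the samples left out follow from the probe sets and samples that enter; for the other settings the cause was not tested. The 175 calls in the 1-hour sample became 272 on the values as deposited, 3 (Nnat, Bin1 and a probe set without a symbol) with the floor at the 40th percentile, 365 with no filter, and 87 to 242 with 1 of the other samples left out, so that this count depends on the treatment of low values and on single samples.

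Lists that did not pass changed the sign of their mean fitted change in some settings, with the cause not tested. With log2 hours the immediate-early list stood at 0.0077 and the neocortex list at 0.026, and with the earlier against the later pair at 0.0087 and 0.045. With 1 sample left out the range was -0.088 to 0.16 for the clock list, -0.19 to 0.26 for immediate-early genes, -0.078 to 0.50 for synaptic plasticity, -0.15 to 0.073 for histones, -0.27 to 0.11 for oxidative phosphorylation, -0.28 to 0.0080 for ribosomal proteins, -0.011 to 0.11 for CA1, -0.13 to 0.020 for CA3 and CA2, -0.20 to 0.032 for meninges, -0.17 to 0.37 for neocortex and -0.027 to 0.45 for generic neurons. Ttr, Per1, Nr1d1, Dbp and Junb in the 1-hour sample and Sgk1 in the 2-hour sample kept their direction under all alternatives run on them, as did the medians of the choroid, generic neuron, oxidative phosphorylation and synaptic lists at 1 hour and of the glucocorticoid, heat shock, NF-kappaB and endothelial lists at 2 hours. Of these medians, that of generic neurons moved to -0.27 with the mean of a gene's probe sets, that of oxidative phosphorylation to 0.29 on the values as deposited and 0.33 with equal medians, and that of NF-kappaB to 0.47 without the 1-hour sample, 0.12 without the 6-hour sample and 0.095 with the mean of a gene's probe sets. The endothelial median moved from 0.57 to 0.36 with the floor at the 40th percentile and to 0.33 without the 6-hour sample, where the heat shock median was 0.16. Dbp was 0.50 without the 2-hour sample and Sgk1 0.42 without the 4-hour sample. Per1 moved to -1.40 with a pseudocount. Signal over background could be judged only by the floor.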

Other observations

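The fit of the 1-hour sample against the other 3, by which genes of that sample were picked here, and the other genes named were chosen after the values had been seen, while the reordering of the times was planned. That fit has no replicate of the 1-hour sample and is no test of it. Some genes not yet described were lower in the 1-hour sample than in each of the others, beside its Gapdh ratio of 4.52. Kif5c, a kinesin motor of axonal transport, had 16.6 against 243 to 458, L1cam, an axonal adhesion molecule, 22.4 against 309 to 357, and Ntrk3, the receptor of neurotrophin 3, 40.9 against 220 to 316. St6galnac6, a sialyltransferase, had 27.3 against 382 to 486. Kif5c, L1cam and St6galnac6 lay below the floor of 35.1 in the 1-hour sample. Nnat, a small membrane protein of neurons, had 891 against 4524 to 5005 (log2 difference -2.40), well above the floor in each sample. Higher in the 1-hour sample were Mapt, the microtubule protein tau, with 9518 against 3925 to 4611 (1.06), Sod1, the cytosolic superoxide dismutase, with 9197 against 4050 to 4401 (1.02), and Nell2, a secreted neuronal glycoprotein, with 6137 against 3322 to 3475 (0.78). So was a probe set unnamed in the annotation used here, with 15204 against 3382 to 3981.

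Probe sets of the same gene parted in that sample. For Nsmf, a protein that signals from NMDA receptors to the nucleus, one probe set lay at -2.37 and another at 1.20. For Psap, the precursor of the saposins, 3 probe sets lay at -2.83, -0.62 and 0.41. The lowest of them had a signal of 10.4 in the 1-hour sample, below the floor, so -2.83 is only an upper bound on its difference. For Errfi1, an inhibitor of the epidermal growth factor receptor, 2 lay at -1.35 and 0.19. The 2 tested probe sets of Actb, beta-actin, lay at -2.17 and -1.40, but its control probe sets did not fall alike. The 3' one had 37515 against 32130 to 33401 in the other samples. The middle one had 22010 against 23768 to 24524, and the 5' one 16054 against 16715 to 18391. The fit picked 55 lowered probe sets with another tested probe set of the gene, and the other was lower in 37 and not lower in 18. The median difference was -1.49 for the 55, which were picked for being low, and -0.13 for the other probe sets of their genes.

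In the list of histones and histone acetylation enzymes, whose medians lay between -0.17 and 0.09, some members were chosen here for their range. Kat2a, an acetyltransferase, had 352, 609, 495 and 103 at 1, 2, 4 and 6 hours (-2.18 in the 6-hour sample), and Hdac3, a deacetylase, 943, 380, 476 and 322 (1.32 in the 1-hour sample). Hdac1 had 162, 289, 113 and 323, and Hdac5 1514, 2315, 2953 and 2305. Of the interneuron markers, Nos1 had 53.2, 186, 221 and 101, Dlx1 383, 149, 305 and 237 and Npy 2572, 1646, 2455 and 2171. The complement genes C1qa and C1qb of microglia had 986, 1407, 1784 and 1556 and 514, 773, 1062 and 804. Ptgds, a prostaglandin synthase of the meninges, had 8209, 6231, 11824 and 4732, and the collagen Col1a1 411, 324, 130 and 323. These are values of single samples, and none was tested as a group beyond the lists of the report.

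The number of probe sets with a trend was set against other orders of the 4 samples. Of all 24 orders, the real one included, 10 gave at least as many probe sets at an unadjusted p under 0.05 as the real 465, and the highest of the others gave 846. Chance order therefore cannot be excluded as the source of these 465.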
